A study of Homo sapiens with 7 samples.

How the data were processed

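Messenger RNA levels were measured on 7 one-colour Affymetrix gene-level arrays hybridised with biotin-labelled material, 1 array per sample, from 2 established human tumour cell lines. Per the labels, BON and NCI-H295R cells were seeded in multi-well plates, and after overnight culture were left untreated or given TNFα at 1 µg/ml for 24 hours before total RNA was extracted. The groups held 1 untreated NCI-H295R array, 2 treated NCI-H295R arrays, 2 untreated BON arrays and 2 treated BON arrays. The labels do not say whether arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

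The deposited table gave log2 values for 33297 probe sets on each array, made by the authors with RMA in Affymetrix Expression Console per the submitters' processing notes, which also name the build hg19 and no software versions. RMA usually corrects background, sets all arrays to the same distribution of probe brightness and summarises probes into a probe set, but the individual steps, filters and annotation release are not given in the sources used here. Setting arrays of such different lines to a common distribution assumes that most genes keep their level, and the summary of probes compresses changes of dim genes. On each pair of arrays 2058 to 2890 probe sets held exactly equal values, so the spread of such genes can be understated.

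Probe sets were named through the platform annotation: 21236 were listed there and 12061 were not, and of those listed 19181 had 1 gene symbol and 2055 had several. Symbols were checked through Entrez identifiers against RefSeq genes of GRCh38.p14, where 19143 were found and 0 symbols needed a change. Because the builds differ, no coordinates are given, and that table served only for names and for which genes are neighbours. The brightest probe set over all arrays stood for each of the 895 genes with several, which left 17958 genes. A gene was tested where the highest of the 4 group means was above the 25th percentile of all values (log2 3.04), which kept 15777 genes.

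Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) with 1 mean per group over all 7 arrays, which share 1 estimate of the spread. The fit had 3 residual degrees of freedom, and 4.92 with those lent by the other genes. The lone untreated NCI-H295R array was assumed to vary like the other arrays. The contrasts were TNFα against untreated in BON, the same in NCI-H295R, the difference of those effects (the interaction), and untreated BON against untreated NCI-H295R. Calls used a Benjamini-Hochberg adjusted p under 0.05, and errors of log2 changes are limma's standard errors (SE). The number of arrays limits the precision: the median SE over genes was 0.08 in BON and 0.10 in NCI-H295R on the log2 scale.

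The design, the alternatives, the rule for named genes and 22 gene lists were fixed before the data were examined. The lists held 473 genes, of which 428 had a gene row and 405 were tested; the others, such as BIRC3, CXCL1 and RIPK1, were not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01 (two-sided, Benjamini-Hochberg over the 22 lists), and again with the correlation estimated from the residuals. The estimated version uses only the 3 residual degrees of freedom, so few lists can pass it. The lists were also tested with fry, which asks whether a list's genes move in the same direction on balance without comparing them with other genes. The rule named, per TNFα contrast, the 10 largest rises and 10 largest falls among called genes whose treated arrays all lay beyond the untreated ones, up to 4 called members of each list or, where none passed, the 2 with the largest change, the 6 highest and 6 lowest differences between the lines, and always TNF, TNFRSF1A, TNFRSF1B, TLR4, LY96, CD14 and NFKBIA. Unnamed loci were passed over. Other members of small list counts, and TSPAN15, were named after their values were seen.

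The alternatives were no filter on dim genes, a filter at the 50th percentile (log2 4.67), quantile normalization again, centring each array on its median, limma with a trend of the spread on level or with robust estimation, a fit on the arrays of 1 line, the suffix of the sample titles as a block, the mean of a gene's probe sets, a minimum change of 1.5-fold, and leaving out each array in turn. The scripts were tested on simulated arrays over 15777 genes, with 200 genes changed in each of 5 simulations. These used the untreated mean of each line and independent noise. The noise had limma's spread of each gene, already drawn toward that of the other genes. For BON they found 74.4% of 1.5-fold changes and 95.6% of 2-fold changes, with a mean of 8.4 false calls. For NCI-H295R the shares were 53.6% and 89.2%, with a mean of 9.4 false calls. The 200 changed genes also held 4-fold and 8-fold changes. In the NCI-H295R data only 12 genes passed, which makes the adjusted threshold stricter than in these simulations. The shares for NCI-H295R can thus be too high for the real arrays. Because the simulated spreads varied less between genes than the real ones, the shares for both lines can be too high.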

Results

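The series compared the response of 2 endocrine tumour lines to tumour necrosis factor alpha (TNFα), an inflammatory cytokine that signals through the receptors TNFRSF1A and TNFRSF1B. BON is a line from a pancreatic neuroendocrine tumour that makes serotonin, and NCI-H295R is a line from an adrenocortical carcinoma that makes steroid hormones. The title of the series also names ASA404, a drug that disrupts tumour vessels, and signalling through TNF receptor 1 and Toll-like receptor 4; arrays of cells given ASA404 were not analysed here. The values were log2 RMA levels, and the array medians lay between 4.61 and 4.73. The difference between arrays of the same group had an SD over the tested genes of 0.19 in untreated BON, 0.17 in treated BON and 0.19 in treated NCI-H295R. Between treated and untreated arrays the SD was 0.22 in NCI-H295R and 0.32 to 0.33 in BON.

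Untreated, the lines differed in genes of their own tissues, among many others. BON held far more chromogranin A (CHGA, a protein of secretory granules; log2 difference 7.52, SE 0.11), secretogranin II (SCG2, 7.03), tryptophan hydroxylase 1 (TPH1, which makes the precursor of serotonin; 6.85) and neurotensin (NTS, 6.76). NCI-H295R held far more of the steroid enzymes HSD3B2 (log2 difference, BON minus NCI-H295R, -7.38, SE 0.24) and CYP17A1 (-7.37, SE 0.17), of MGARP (-6.42) and of the cholesterol carrier STAR (-6.02). Of 24 tested neuroendocrine genes 19 were higher in BON and 1, UCHL1 (-0.72), was lower, the same numbers as adjusted over the list alone. Camera gave this list an adjusted p of 1e-06 (adjusted p = 0.198 with an estimated correlation). Of 21 tested steroidogenesis genes 16 were lower in BON and 2, CYB5A (1.20) and INHA (1.16), were higher, again the same numbers adjusted over the list alone. The steroidogenesis list ranked below other genes (camera adjusted p = 0.00086; adjusted p = 0.25 with an estimated correlation). The dimmer line lay near or below the filter level for most of the largest differences, so their sizes and order are not exact. Highest in BON were S100A3 (8.62), CYP2B6 (7.94), PLAC8 (7.89), ADGRL4 (7.84), SEMA3A (7.83) and TMBIM1 (7.82), and lowest were SPARC (-8.21), SERPINA5 (-7.62), CPB1 (-7.62), NPY6R (-7.61), A2M (-7.45) and IGFBP7 (-7.44).

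The receptors named in the title of the series, and some related genes, had different measured levels before treatment. Toll-like receptor 4 (TLR4) was 4.08-fold higher in untreated BON than in untreated NCI-H295R (log2 2.03, SE 0.10, limma adjusted p = 7.93e-05), and its partner LY96 was also higher (log2 1.81, SE 0.15, limma adjusted p = 0.000439). In untreated NCI-H295R TLR4 lay at 3.48, near the filter level of 3.04, and LY96 at 2.61, below it, so the sizes of both differences are not exact. TNFRSF1A was 1.46-fold higher in BON (limma adjusted p = 0.00473), whereas TNFRSF1B was lower by a log2 difference of -0.88 (SE 0.17, limma adjusted p = 0.00792) at dim levels in both lines. CD14, a co-receptor of TLR4, did not pass (log2 -0.42, limma adjusted p = 0.130). Of 17 tested TLR4 signalling genes 11 were higher in BON and TBK1 (-1.67) and MAP3K7 (-1.39) were lower, with the same numbers adjusted over the list alone. The list passed camera (adjusted p = 0.0193; adjusted p = 0.266 with an estimated correlation). Camera also ranked the unfolded protein response higher in BON (adjusted p = 0.00968; adjusted p = 0.352 with an estimated correlation), and angiogenesis and hypoxia (adjusted p = 0.0102; adjusted p = 0.266 with an estimated correlation). The same held for Cell adhesion and leukocyte docking (camera adjusted p = 0.031; adjusted p = 0.266 with an estimated correlation; 0.0551 after median centring). AP-1 and immediate early genes also ranked higher (camera adjusted p = 0.031; adjusted p = 0.327 with an estimated correlation; 0.0639 without BON_control replicate 2). In all, 9174 of 15777 genes differed between the untreated lines by limma with Benjamini-Hochberg adjustment, 4117 higher and 5057 lower in BON, in a comparison that rests on a single NCI-H295R array. Which direction was more frequent depended on scaling. There were 4606 higher and 4674 lower after quantile normalization again, and 4731 higher and 4540 lower after median centring.

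In BON, TNFα raised a broad set of inflammatory genes. Complement C3 rose 46.7-fold (log2 5.55, SE 0.21, limma adjusted p = 0.00189, n = 2 against 2). The cytokine IL32 rose 22.7-fold (log2 4.51, SE 0.20) and the adhesion receptor ICAM1 15.0-fold (log2 3.90, SE 0.10). TNFRSF9, a co-stimulatory receptor of the TNF family, rose 13.9-fold (log2 3.80, SE 0.16). The NF-kB inhibitors TNFAIP3 and NFKBIA rose 11.0-fold (SE 0.05 on the log2 scale) and 10.1-fold (SE 0.06). TDO2, which opens tryptophan breakdown to kynurenine, rose 9.41-fold, the T cell ligand ICOSLG 8.09-fold, the urokinase gene PLAU 7.32-fold and TNF itself 7.09-fold (log2 2.83, SE 0.11). C3 and TNF started near the filter level of log2 3.04, so their folds are not exact. The 10 largest falls were smaller. The matrix proteoglycan BGN fell by 1.61 on the log2 scale (SE 0.17), the glutamine transporter SLC38A3 fell by 1.48 (SE 0.10) and GLDN fell by 1.33. CALCRL, a part of the adrenomedullin receptor, fell by 1.29, PRKG2 fell by 1.25 and TCP11L2 fell by 1.24. The transsulfuration enzyme CTH fell by 1.22 and the mitochondrial coactivator PPARGC1A fell by 1.19. The stress gene DDIT4 fell by 1.18 and the potassium channel gene KCNT2 fell by 1.15. By limma with Benjamini-Hochberg adjustment 2090 of 15777 genes changed, 1310 up and 780 down, and 612 of them by at least 1.5-fold (415 up, 197 down). The balance of directions depended on scaling, with 988 up and 1079 down after quantile normalization again and 932 up and 1094 down after median centring. The count rested on few arrays: it was 227 without BON_control replicate 1, 183 without BON_control replicate 2, 86 without BON_TNF replicate 1, 3 without BON_TNF replicate 2 and 1208 without either NCI_TNF replicate.

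**Figure D1:**
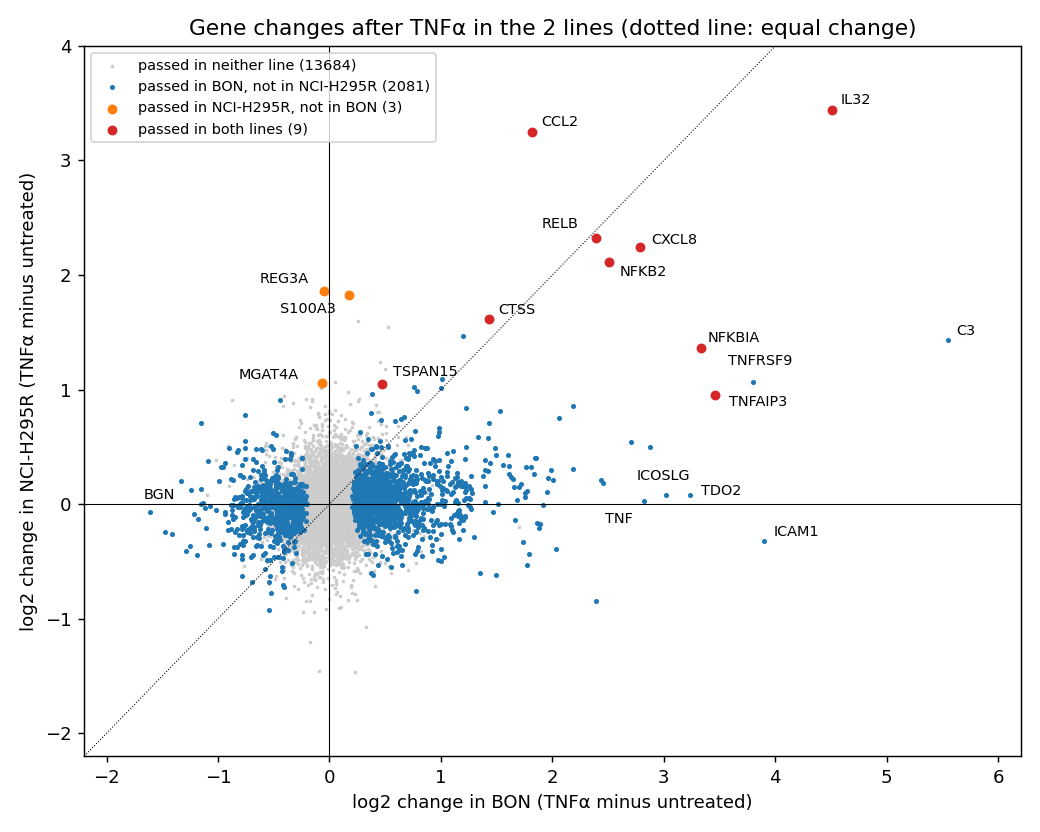
Log2 change after TNFα in BON (horizontal axis) against that in NCI-H295R (vertical axis), 1 point per tested gene (15777), coloured by the line in which it passed the limma test. The 9 genes that passed in both lines lie in the upper right, with IL32 at 4.51 in BON and 3.44 in NCI-H295R, while ICAM1 (3.90 in BON, -0.32 in NCI-H295R) lies near the horizontal axis.

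Genes of the NF-kB pathway and of its feedback rose for the most part in BON. Of 21 tested members 18 rose (19 adjusted over the list alone), among them TNFAIP3, NFKBIA, NFKB2 (5.68-fold, log2 2.51, SE 0.11) and RELB (5.26-fold, log2 2.39, SE 0.13). Against all other genes, camera returned an adjusted p of 4.18e-15 (adjusted p = 0.0737 with an estimated correlation). Of 12 tested chemokines 7 rose (8 adjusted over the list alone): the neutrophil attractants CXCL8 (6.90-fold, SE 0.08) and CXCL2 (3.57-fold), the monocyte attractant CCL2 (3.53-fold) and CX3CL1 (3.06-fold) led. The camera test of the group gave an adjusted p of 3.2e-06 (adjusted p = 0.1 with an estimated correlation). Of 16 inflammatory cytokines and growth factors 6 rose (6 adjusted over the list alone), led by IL32, TNF, LTB (5.49-fold) and CSF1 (2.23-fold). Camera gave this list an adjusted p of 0.00156 (adjusted p = 0.114 with an estimated correlation).

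Most MHC class I genes and a part of the interferon genes also rose in BON. Of 18 tested genes of MHC class I presentation 12 rose (16 adjusted over the list alone). Among them were the peptide-loading protein TAPBP (2.72-fold, log2 1.44, SE 0.06), the immunoproteasome subunit PSMB9 (2.26-fold), the trimming peptidase ERAP2 (2.07-fold) and the peptide transporter TAP1 (1.93-fold). The class I list ranked above other genes (camera adjusted p = 9.13e-11; adjusted p = 0.0737 with an estimated correlation). Of 38 interferon-response genes 11 rose (12 adjusted over the list alone), led by OAS1 (3.38-fold, SE 0.09), IRF1 (2.41-fold), OAS3 (2.33-fold) and the RNA sensor RIGI (1.78-fold). The list passed camera (adjusted p = 3.11e-05; adjusted p = 0.09 with an estimated correlation). Of 11 MHC class II genes only the protease CTSS passed (2.70-fold), and 2 genes rose adjusted over the list alone. CTSS lay at 3.38 in untreated BON, near the filter level, so its fold is not exact. Camera did not call this list (adjusted p = 0.269).

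Adhesion and matrix genes rose in part. Of 20 tested adhesion genes 12 rose (12 adjusted over the list alone), led by ICAM1 and the integrins ITGB8 (3.26-fold, SE 0.08) and ITGAV (2.32-fold), with the laminin chain LAMB3 at 1.96-fold. Against all other genes, camera returned an adjusted p of 3.26e-05 (adjusted p = 0.09 with an estimated correlation). Of 18 matrix and plasminogen genes 6 rose (7 adjusted over the list alone) and 1, the protease inhibitor TIMP3, fell by 0.63 on the log2 scale. PLAU was joined by MMP7 (2.38-fold), the protease inhibitor SERPINE2 (2.34-fold) and the urokinase receptor PLAUR (2.21-fold). MMP7 lay at 3.22 in untreated BON, near the filter level, so its fold is not exact. The camera test of the group gave an adjusted p of 0.0171 (adjusted p = 0.14 with an estimated correlation). Of 24 AP-1 and immediate early genes 9 rose (9 adjusted over the list alone), with JUN at 3.39-fold (SE 0.09), CCN1 and JUND at 1.68-fold each and JUNB at 1.59-fold. Camera gave this list an adjusted p of 0.00139 (adjusted p = 0.139 with an estimated correlation).

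A part of the genes that carry the TNF receptor and TLR4 signals rose in BON. Of 20 tested TNF receptor components 5 rose (5 adjusted over the list alone). They were the necroptosis effectors MLKL (1.70-fold, SE 0.05) and RIPK3 (1.45-fold), the caspase-8 regulator CFLAR (1.51-fold), FADD (1.28-fold) and CASP8 (log2 0.32). The list did not pass camera (adjusted p = 0.335). Of 17 TLR4 components 7 rose (8 rose and 1 fell adjusted over the list alone), with the kinases IRAK2 (6.51-fold, log2 2.70, SE 0.07) and IKBKE (5.42-fold) far ahead of TRAF3 (2.02-fold) and the adaptor MYD88 (1.56-fold). The TLR4 list ranked above other genes (camera adjusted p = 0.000748; adjusted p = 0.114 with an estimated correlation). The receptors themselves did not pass in BON. TLR4 had a log2 change of 0.34 (SE 0.08, limma adjusted p = 0.0651) and LY96 0.30 (SE 0.13). The value was -0.22 for TNFRSF1A (SE 0.07, limma adjusted p = 0.125), -0.08 for CD14 (SE 0.16) and 0.00 for TNFRSF1B (SE 0.14).

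Some cell death genes rose in BON and others fell. Of 26 tested apoptosis genes 7 rose and 3 fell in BON (7 and 4 adjusted over the list alone). The BH3 gene BID rose 1.63-fold and the death receptor TNFRSF10B 1.59-fold. The BH3 gene HRK fell by 0.61 on the log2 scale, the survival gene BCL2 fell by 0.54 and BCL2A1 fell by 0.30. As a list they did not stand apart (camera adjusted p = 0.269). Of 17 p53 targets TNFRSF10B rose and SESN2 fell by 0.69 (4 rose and 1 fell adjusted over the list alone). The list did not pass camera (adjusted p = 0.582). Of 27 cell cycle genes CDC20 rose (log2 0.34, SE 0.07) and TOP2A fell by 0.33 (SE 0.07), and adjusted over the list alone 0 passed in limma, where CDC20 and TOP2A alone passed over all genes. The group as a whole did not pass (camera adjusted p = 0.975).

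Some differentiation and stress genes rose in BON and others fell. Of 24 neuroendocrine genes 5 fell and 2 rose (7 and 2 adjusted over the list alone). The somatostatin receptor SSTR5 fell by 0.79 on the log2 scale (SE 0.09) and the vesicular monoamine transporter SLC18A1 fell by 0.64 (SE 0.08). SNAP25 fell by 0.47, CPE fell by 0.41 and SYT1 fell by 0.35. The somatostatin receptor SSTR2 rose 2.28-fold (log2 1.19, SE 0.24) and NTS rose (log2 0.38). The list lay below other genes (camera adjusted p = 0.0159; adjusted p = 0.139 with an estimated correlation). For neuroendocrine secretion and serotonin this call was lost without BON_control replicate 1 (camera adjusted p = 0.0504) and without BON_TNF replicate 2 (camera adjusted p = 0.0698). Of 18 unfolded protein response genes 4 fell (4 adjusted over the list alone). The falls were in TRIB3, by a log2 change of -0.85, DDIT3 by -0.83, CHAC1 by -0.83 and ASNS by -0.45. PDIA4 rose (log2 0.31; 3 rose adjusted over the list alone). As a list they did not stand apart (camera adjusted p = 0.453). Of 19 angiogenesis and hypoxia genes THBS1, which codes for an inhibitor of vessel growth, rose 2.15-fold, NDRG1 fell by 0.71, VEGFA fell by 0.46 (SE 0.08) and SLC2A1 fell by 0.34 (1 rose and 4 fell adjusted over the list alone). The group as a whole did not pass (camera adjusted p = 0.113). Of 17 cholesterol genes 6 rose and STARD4 fell by 0.34 (8 and 1 adjusted over the list alone), with MVD at 1.45-fold, IDI1 at 1.30-fold, NSDHL at 1.29-fold and SQLE at 1.27-fold. Camera did not call this list (adjusted p = 0.0511). Of 21 steroidogenesis genes POR rose (log2 0.25), SOAT1 fell by 0.37 and AKR1C3 fell by 0.35, the same 1 and 2 adjusted over the list alone. The list did not pass camera (adjusted p = 0.0784).

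Some markers of other cell types changed in BON. Of 10 fibroblast markers FAP fell by 0.64 on the log2 scale from a dim level (0 adjusted over the list alone in limma; camera adjusted p = 0.318). Of 8 leukocyte markers ITGAM (1.81-fold) and CD68 (1.72-fold) rose (3 adjusted over the list alone; camera adjusted p = 0.0823, which became 0.0362 for Leukocyte markers after quantile normalization again and 0.0479 after median centring). Of 8 endothelial markers PECAM1 rose 1.89-fold (log2 0.92, SE 0.05), the 1 gene that also passed adjusted over the list alone. As a list they did not stand apart (camera adjusted p = 0.313).

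**Figure D2:**
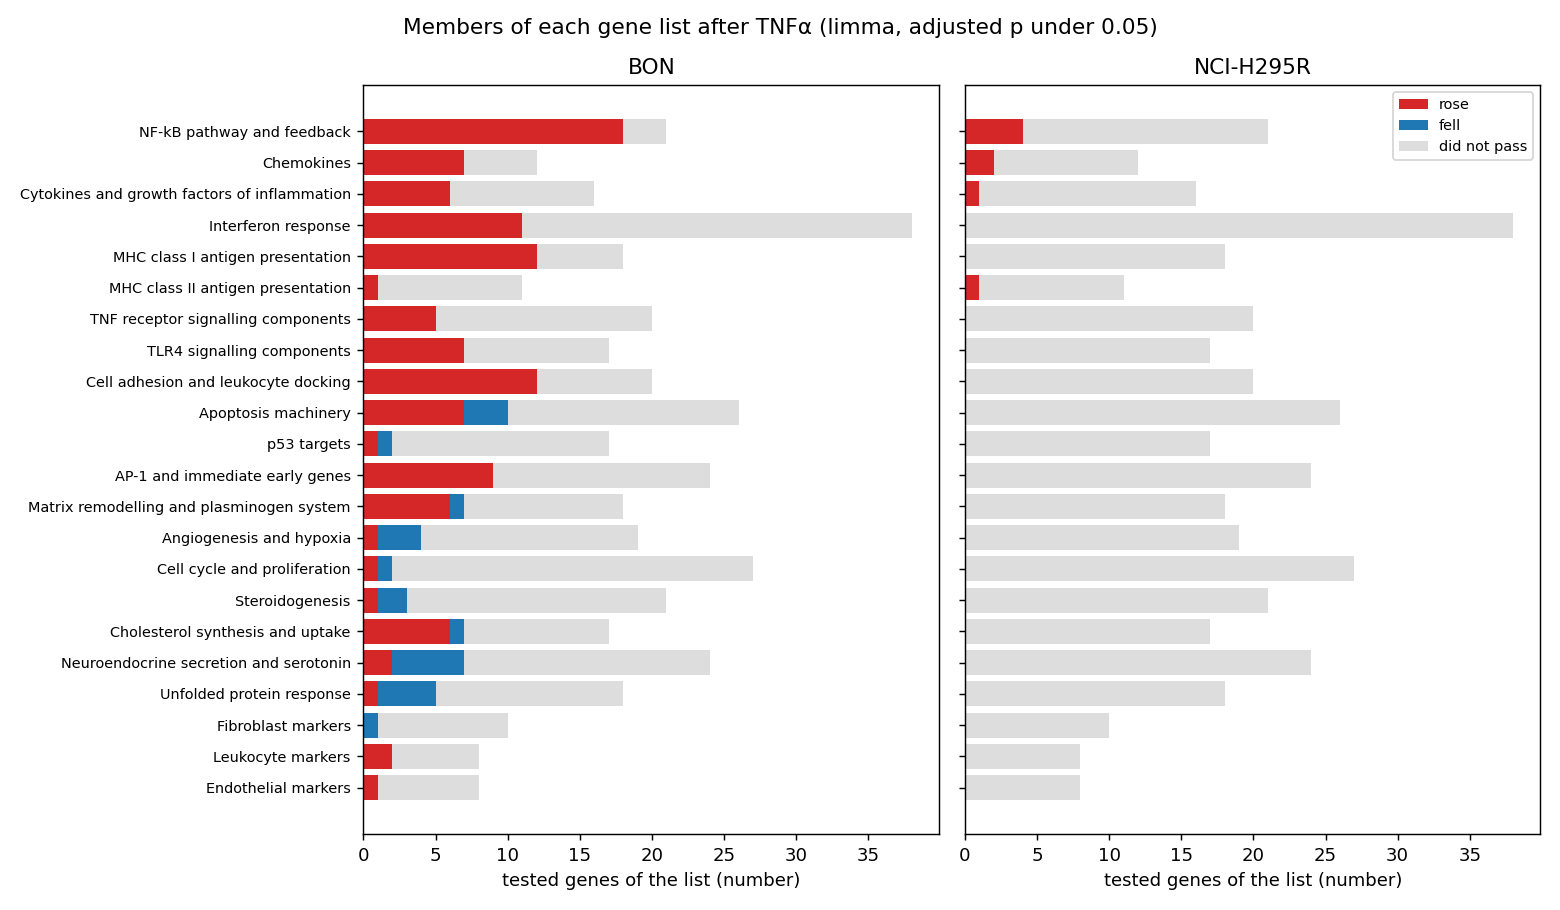
Number of tested genes of each list (horizontal axis) that rose, fell or did not pass the limma test after TNFα, in BON (left) and in NCI-H295R (right). In BON 18 of 21 NF-kB genes rose, and in NCI-H295R 4 of 21 did.

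In NCI-H295R, TNFα raised a short list of genes led by cytokines and NF-kB subunits. IL32 rose 10.9-fold (log2 3.44, SE 0.24, limma adjusted p = 0.0436, n = 2 against 1) and CCL2 9.53-fold (log2 3.25, SE 0.13, limma adjusted p = 0.0243). RELB rose 4.99-fold (log2 2.32, SE 0.16), CXCL8 4.73-fold (log2 2.24, SE 0.10) and NFKB2 4.33-fold (log2 2.12, SE 0.14). The antimicrobial lectin REG3A rose 3.64-fold (log2 1.86, SE 0.11), the calcium-binding protein gene S100A3 3.54-fold (log2 1.82, SE 0.10) and CTSS 3.07-fold. The other genes were NFKBIA at 2.57-fold (log2 1.36, SE 0.08), the glycosyltransferase gene MGAT4A at 2.08-fold, TSPAN15 with a log2 change of 1.05 and TNFAIP3 at 1.93-fold. These 12 genes were all that passed limma with Benjamini-Hochberg adjustment. In limma 0 genes fell, against 828 lower and 920 higher at an unadjusted p under 0.05. Limma with a trend called 30 up and 9 down while robust limma called 12 up and 0 down. With the other scalings the split was 17 up and 1 down (quantile normalization again) or 17 up and 4 down (median centring). The count fell to 1 without BON_control replicate 1 or BON_control replicate 2. It was 0 without NCI_TNF replicate 1 (1762 genes at an unadjusted p under 0.05), NCI_TNF replicate 2 (1815), BON_TNF replicate 1 (1682) or BON_TNF replicate 2 (1682), all in limma.

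The gene lists in NCI-H295R repeated a part of this. Of 21 NF-kB genes 4 rose, RELB, NFKB2, NFKBIA and TNFAIP3 (12 adjusted over the list alone). The camera test of the group gave an adjusted p of 3.13e-15 (adjusted p = 0.146 with an estimated correlation). Of 12 chemokines CCL2 and CXCL8 rose (3 rose and 1 fell adjusted over the list alone). Camera gave this list an adjusted p of 0.00341 (adjusted p = 0.389 with an estimated correlation). The 18 MHC class I genes ranked above other genes (camera adjusted p = 4.88e-05; adjusted p = 0.173 with an estimated correlation). Singly 0 of them passed in limma, against 7 higher at an unadjusted p under 0.05, 1 with a trend, 0 with robust estimation and 5 adjusted over the list alone. HLA-B had a log2 change of 0.37 (SE 0.06) and TAPBP 0.36 (SE 0.07). The 17 TLR4 components also ranked higher (camera adjusted p = 0.0264; adjusted p = 0.389 with an estimated correlation), with TRAF3 at 1.09 (SE 0.11, limma adjusted p = 0.0815) and IRAK2 at 0.54 (SE 0.09). Of these 0 passed singly in limma, against 4 at an unadjusted p under 0.05, 1 with a trend, 0 with robust estimation and 2 adjusted over the list alone. For the TLR4 signalling components the call was lost without NCI_TNF replicate 1 (camera adjusted p = 0.228) and without BON_TNF replicate 1 or 2 (camera adjusted p of 0.0653 each), and with no filter on dim genes it was 0.107.

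The remaining lists did not pass camera in NCI-H295R. IL32 was the 1 of 16 cytokines to pass (1 adjusted over the list alone; camera adjusted p = 0.736) and CTSS the 1 of 11 MHC class II genes (2 adjusted over the list alone). Camera did not call the class II list (adjusted p = 0.258). Of 20 adhesion genes 0 passed in limma, against 8 higher and 3 lower at an unadjusted p under 0.05, 0 with a trend and 0 with robust estimation. There were 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.122). LAMB3 had a log2 change of 0.60 (SE 0.08) and ITGA3 0.47 (SE 0.07). Among interferon genes the largest values were ISG15 at 0.57 (SE 0.16) and IFIH1 at 0.44 (SE 0.07; list camera adjusted p = 0.324). Among AP-1 genes they were JUNB at 0.76 (SE 0.13) and FOSL1 at 0.68 (SE 0.24; camera adjusted p = 0.523). Matrix genes had TNC at 0.92 (SE 0.27) and PLAU at 0.50 (SE 0.11; camera adjusted p = 0.258). Hypoxia genes had EPAS1 at 0.86 (SE 0.07, limma adjusted p = 0.0570) and KDR at -0.30 (camera adjusted p = 0.486). Adjusted over the list alone, 3 AP-1 genes, 1 hypoxia gene and 1 of the apoptosis genes rose. Further named values were TNFRSF10B 0.44 and BID 0.40 in apoptosis (camera adjusted p = 0.973), TP53I3 0.33 in p53 targets (camera adjusted p = 0.973), and CCND1 0.21 and BIRC5 -0.19 in the cell cycle (camera adjusted p = 0.324). TNF receptor genes had TNFRSF1B at 0.54 and TRADD at 0.42 (camera adjusted p = 0.973). Steroidogenesis, the specialised function of this line, had HSD3B1 at 0.59 (SE 0.47) and HSD17B1 at -0.44 (SE 0.20; camera adjusted p = 0.829). Cholesterol synthesis had INSIG1 at -0.21 and EBP at -0.20 (camera adjusted p = 0.486). Neuroendocrine genes had SYP at -0.49 and INSM1 at 0.49 (camera adjusted p = 0.763), and the unfolded protein response had CHAC1 at -0.37 and DDIT3 at -0.22 (camera adjusted p = 0.523).

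Markers of other cells did not pass in NCI-H295R either. Fibroblast markers had COL1A1 at 0.41 and THY1 at -0.26 (camera adjusted p = 0.973). Leukocyte markers had LAPTM5 at 0.47 and NKG7 at -0.11 (camera adjusted p = 0.973), and endothelial markers had ESAM at 0.21 and EGFL7 at 0.19 (camera adjusted p = 1). TNF itself had a log2 change of 0.03 (SE 0.14), TLR4 -0.03 (SE 0.10), TNFRSF1A -0.04 (SE 0.09), LY96 0.21 (SE 0.15) and CD14 -0.19 (SE 0.20) in this line.

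The interaction asked which genes responded differently in the 2 lines. ICAM1 showed the largest excess in BON (difference of log2 changes 4.23, SE 0.15, limma adjusted p = 0.0109), followed by C3 (4.12, SE 0.33), PSTPIP2 (3.24, SE 0.15), TDO2 (3.15, SE 0.20), ICOSLG (2.93, SE 0.17) and TNF (2.80, SE 0.18). The feedback inhibitor NFKBIA rose more in BON (1.97, SE 0.10, limma adjusted p = 0.0178), from an untreated level that was lower than in NCI-H295R by a log2 difference of -1.49. The lowest differences were those of REG3A (-1.91, SE 0.14), LIMD1-AS1 (-1.86, SE 0.15), S100A3 (-1.65, SE 0.14), SLC9B1 (-1.54, SE 0.18), GLDN (-1.53, SE 0.20) and DLG2 (-1.47, SE 0.14). REG3A lay below the filter level on all BON arrays and SLC9B1 on all NCI-H295R arrays, as did PSTPIP2 on the treated NCI-H295R arrays, so the sizes and ranks of these differences are not exact. By limma with Benjamini-Hochberg adjustment 267 genes differed, 189 with the higher change in BON and 78 with the lower. Without any 1 of NCI_TNF replicate 1, NCI_TNF replicate 2, BON_control replicate 1, BON_control replicate 2, BON_TNF replicate 1 or BON_TNF replicate 2 the count was 0 in limma, with 2598 to 3014 genes at an unadjusted p under 0.05.

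Differences between the lines gathered in the inflammatory lists. Of 21 NF-kB genes 6 rose more in BON (9 adjusted over the list alone; camera adjusted p = 1.04e-06; adjusted p = 0.178 with an estimated correlation). So did 4 of 18 MHC class I genes (8 adjusted over the list alone; camera adjusted p = 1.25e-06; adjusted p = 0.178 with an estimated correlation). Among 38 interferon genes 5 rose more in BON (7 adjusted over the list alone), and the list ranked above other genes (camera adjusted p = 0.00257; adjusted p = 0.178 with an estimated correlation). The class I genes were TAPBP (1.08), PSMB9 (0.97), ERAP1 (0.83) and PSME1 (0.74), and the interferon genes OAS1 (1.69), IRF1 (1.14), OAS3 (1.11), RIGI (0.84) and IFITM3 (0.78). Of 20 adhesion genes 5 rose more in BON, ICAM1, ITGB8 (1.56), ITGB6 (1.17, below the filter level in NCI-H295R), ITGAV (1.03) and CD47 (0.63), against 11 higher and 3 lower adjusted over the list alone. The list passed camera (adjusted p = 0.00661; adjusted p = 0.178 with an estimated correlation). TNF and LTB (2.27) did so among 16 cytokines (4 adjusted over the list alone). The list passed camera (adjusted p = 0.00358; adjusted p = 0.178 with an estimated correlation). Chemokines were split: CX3CL1 (1.28), CXCL11 (1.10, below that level in untreated NCI-H295R) and CCL28 (0.69) rose more in BON and CCL2 less (-1.43), with 6 and 1 adjusted over the list alone. Against all other genes, camera returned an adjusted p of 0.0196 (adjusted p = 0.261 with an estimated correlation). JUN (1.44) and JUND (0.78) passed among 24 AP-1 genes (6 higher and 2 lower adjusted over the list alone). Against all other genes, camera returned an adjusted p of 0.0284 (adjusted p = 0.261 with an estimated correlation). The cholesterol list also passed (camera adjusted p = 0.0284; adjusted p = 0.263 with an estimated correlation), and its call was lost for Cholesterol synthesis and uptake after quantile normalization again, where its camera adjusted p was 0.0552. For Cholesterol synthesis and uptake the call was also lost without NCI_TNF replicate 2 (camera adjusted p = 0.0584), BON_control replicate 1 (0.104) or BON_TNF replicate 2 (0.0526). For AP-1 and immediate early genes it was lost without BON_control replicate 1 (camera adjusted p = 0.0628) or BON_TNF replicate 1 (0.101). The filter at the 50th percentile lost the difference for Chemokines (camera adjusted p = 0.0666), AP-1 genes (0.0955) and cholesterol genes (0.0569).

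The genes that rose in NCI-H295R overlapped those that rose in BON. Of the 12 genes that rose in NCI-H295R, 9 also rose in BON, against 0.996 expected from independent lists: IL32, CCL2, RELB, CXCL8, NFKB2, CTSS, NFKBIA, TSPAN15 and TNFAIP3 (hypergeometric p = 3.19e-08, exact, one-sided). That test treats genes as independent, and both contrasts share each gene's estimate of the spread, so its p may be too small. In fits added after seeing the data this overlap was 1 without BON_control replicate 1 or BON_control replicate 2. It was 0 by limma without NCI_TNF replicate 1, NCI_TNF replicate 2, BON_TNF replicate 1 or BON_TNF replicate 2, where 0 NCI-H295R genes passed (1682 to 1815 at an unadjusted p under 0.05). REG3A (log2 change in BON -0.04), S100A3 (0.17) and MGAT4A (-0.07) did not pass in BON. Among the 1310 genes that rose in BON 60.8% also lay above 0 in NCI-H295R, where 47.4% of all genes did, and their median log2 change was 0.04 there against 0.45 in BON, a value raised by the selection on BON itself. Across all tested genes, which are not independent replicates, the changes of the lines correlated with r = 0.18 and Spearman's rho = 0.136.

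**Figure D3:**
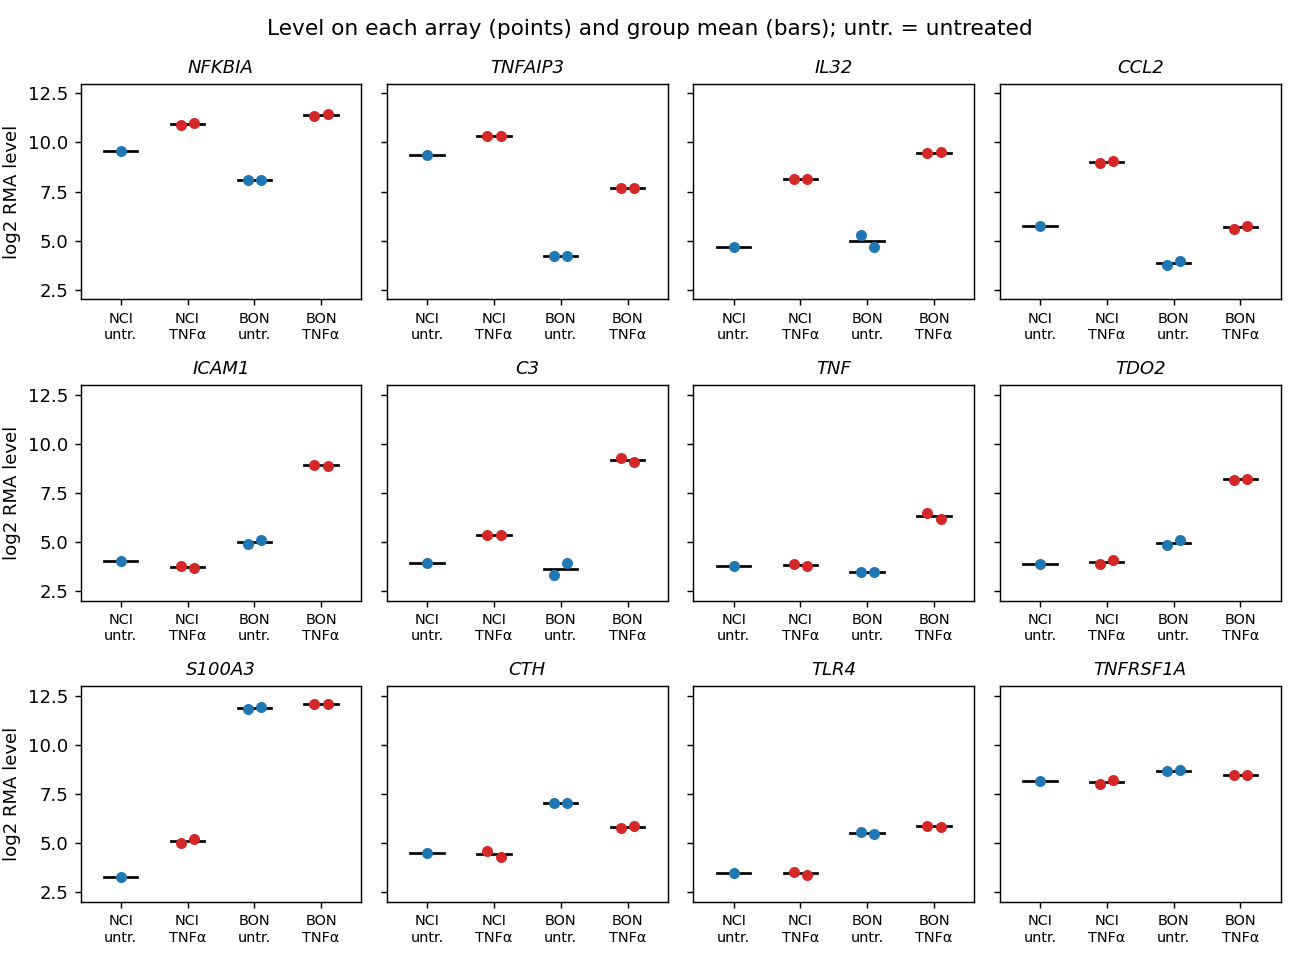
Log2 RMA level (vertical axis) of 12 genes on each of the 7 arrays (points) with the mean of each group (bars), untreated and after TNFα, in NCI-H295R (NCI) and BON. NFKBIA rose in both lines to 10.93 and 11.41, TNF rose in BON to 6.29, and S100A3 rose in NCI-H295R to 5.10 against 11.90 in untreated BON.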

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

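The tests of a lone array, of the normalization and of carried-over RNA reported here were chosen after the results they bear on were seen; the test of the size of the changes was written first.

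The change after TNFα differed between BON and NCI-H295R for 267 genes by limma's interaction test with Benjamini-Hochberg adjustment, and 41 of the genes picked by the naming rule were among them. Besides ICAM1 (difference of log2 changes, BON minus NCI-H295R, 4.23), C3 (4.12), PSTPIP2 (3.24), TDO2 (3.15), ICOSLG (2.93) and TNF (2.80), these were TNFRSF9 (2.73), TNFAIP3 (2.51), PLAU (2.38), LTB (2.27), IKBKE (2.23), IRAK2 (2.16), NFKBIA (1.97), OAS1 (1.69), ITGB8 (1.56), JUN (1.44), CX3CL1 (1.28), IRF1 (1.14), OAS3 (1.11), SERPINE2 (1.10), TAPBP (1.08), PECAM1 (1.06), ITGAV (1.03), PSMB9 (0.97), MLKL (0.92), THBS1 (0.91), RIGI (0.84) and JUND (0.78) with the higher change in BON. The change was lower in BON for NDRG1 (-0.82), EPAS1 (-0.90), DDIT4 (-1.05), MGAT4A (-1.13), SLC38A3 (-1.23), TCP11L2 (-1.36), CCL2 (-1.43), DLG2 (-1.47), GLDN (-1.53), SLC9B1 (-1.54), S100A3 (-1.65), LIMD1-AS1 (-1.86) and REG3A (-1.91). Without any 1 array of the treated groups or of untreated BON (NCI_TNF replicate 1 or 2, BON_control replicate 1 or 2, BON_TNF replicate 1 or 2) limma called 0 genes, with 2598 to 3014 at an unadjusted p under 0.05. TNFAIP3 rose more in BON from a far lower level, 4.22 untreated and 7.68 treated. In untreated NCI-H295R it already lay at 9.37, above both. PSTPIP2 rose in BON (log2 2.39, SE 0.09) and lay below the filter level on the treated NCI-H295R arrays, so its difference is not exact. SLC9B1 fell in BON by 0.76, and on all NCI-H295R arrays it lay below the filter level, so its difference is not exact.

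Far more genes passed in BON (2090) than in NCI-H295R (12). A lone untreated array widens the error and can cost calls, and BON fits with 1 array of either group left out called between 3 and 227 genes. For the 169 genes at least 2-fold higher in the first pair of BON arrays, the median log2 change was 1.25 in the second BON pair. It was 0.14 in NCI-H295R, a ratio of 0.109. Its upper 95% bound of 0.148 came from resampling genes with the arrays held fixed, so it holds no error of the lone array. The genes were also chosen in BON, so the ratio does not tell how many changes in other genes were missed. On these arrays, genes that rose in BON changed less in NCI-H295R, and a part played by the lone array stays open. Quantile normalization again or median centring gave at most 21 genes in NCI-H295R and 2067 or 2026 in BON. Both settings started from the deposited RMA values and cannot undo the normalization already in them. They therefore cannot decide whether the normalization across both lines played a part, which stays open. Smaller changes in NCI-H295R are consistent with the ratio of 0.109 and remain as a hypothesis, while a difference in how much active TNFα reached the cells of each line was not tested.

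S100A3 rose in NCI-H295R, from 3.28 to 5.10, and is among the genes with the greatest excess in BON (11.90 untreated). BON RNA carried into the treated NCI-H295R samples could raise it, and would need a share of 0.574%. The check took genes above the 50th percentile of all values in untreated NCI-H295R. Genes near background were thus left out, although S100A3 itself started there. Only 8 of the genes taken would be raised by that share by at least 0.3 on the log2 scale. Their predicted median was 0.356 and their observed median -0.0456 (95% bounds -0.147 and 0.111), too few genes to decide, so this cause stays open. S100A4 and S100A6, also higher in BON, had values of -0.52 (limma adjusted p = 0.165) and -0.61 (limma adjusted p = 0.190) in NCI-H295R, and no biological explanation was tested.

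Probe sets without exactly 1 gene symbol were left out of the gene tests. Among the 9542 of them above the filter, 86 changed in BON by limma with Benjamini-Hochberg adjustment over those probe sets, 38 up and 48 down, of which 19 carried several symbols and 67 were unlisted in the annotation.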

How the results depend on the processing

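The count of 2090 in BON became 1050 with the replicate block, 612 at a minimum of 1.5-fold and 1208 with only the arrays of the line, and 3 to 2090 with 1 array left out. The other planned settings gave 1903 to 2701. The count of 12 in NCI-H295R became 2 without the filter and 35 with the filter at the 50th percentile, where fewer genes were tested, 21 with median centring, 39 with a trend, 1 with the replicate block, 0 with only the arrays of the line and 0 to 1 with 1 array left out, where the contrast could be fitted. The same 12 genes were within the calls of the stricter filter, of both scalings and of the trend. The count of 267 differences became 459 with the filter at the 50th percentile, 557 with a trend, and 0 with the replicate block (2594 at an unadjusted p under 0.05 in limma) and with 1 array left out of any group but untreated NCI-H295R, without which it cannot be fitted. Fits with fewer arrays or a block have fewer residual degrees of freedom; beyond that the cause was not tested. The comparison of the untreated lines gave 6593 to 9349 calls under every setting without an array left out. The replicate block rests on a title suffix that did not pair the samples: deviations correlated at -0.03, -0.05 and 0.08 between groups.

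With an estimated correlation 0 lists passed camera in each comparison (main 10 in BON, 4 in NCI-H295R, 8 for the difference, 7 untreated). Fry called 17, 4, 16 and 17 lists in the same order. With only 3 residual degrees of freedom the estimated version cannot easily give a low p. For the NF-kB list in BON, with 18 of 21 genes risen, camera gave an unadjusted p of 0.0067 there. Its 0 calls therefore cannot tell whether correlation between genes accounts for the calls at the preset correlation. The overlap of 9 genes became 2 without the filter and 18 with the filter at the 50th percentile. In settings added after seeing the data it was 20 with a trend, 1 with the replicate block, 0 with only the arrays of the line, 0 to 1 with 1 array left out, and 9 with robust estimation or the mean of probe sets. Signs turned only for named genes that had not passed. With median centring the log2 change was -0.0498 for TNFRSF1B in BON and -0.0038 for TNF in NCI-H295R, and with the replicate block it was 0.0281 for TLR4 in NCI-H295R. With 1 array left out the values ran in BON from -0.159 to 0.165 for TNFRSF1B and from -0.159 to 0.0074 for CD14. In NCI-H295R they ran from -0.0242 to 0.078 for TNF, from -0.124 to 0.0493 for TNFRSF1A, from -0.124 to 0.0605 for TLR4 and from -0.415 to 0.0265 for CD14. The differences between the lines ran from -0.0493 to 0.24 for LY96 and from -0.102 to 0.339 for CD14. EPAS1 in NCI-H295R passed after quantile normalization again (0.85). Of the other named values, 41 lost their call with the replicate block, 4 with the mean of probe sets and 2 with either scaling; with 1 array left out 0 to 106 did. Quantile normalization and centring moved the median of all genes by less than 0.1 in every comparison. Signal over background limits dim genes such as CD14, and TNFRSF1B in BON, whose levels lay near the filter.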

Other observations

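The test of amino acid genes and that of neighbouring genes reported here were written before their results were seen, and the genes described were chosen after their values were seen unless stated otherwise.

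Several genes of amino acid supply fell in BON after TNFα. Besides CTH, the amino acid transporter genes SLC7A5 (log2 change -0.86, SE 0.06, limma adjusted p = 0.00414) and SLC7A11 (-0.63, SE 0.06), the serine synthesis genes PSAT1 (-0.65) and PHGDH (-0.46), the transsulfuration gene CBS (-0.53), the mitochondrial folate gene MTHFD2 (-0.49) and the tRNA ligase gene CARS1 (-0.70) fell. SLC7A5 and MTHFD2 also differed from NCI-H295R in the interaction test (limma adjusted p = 0.0312 and 0.0314), where their values were 0.05 and 0.24. Several of these are known targets of the stress transcription factor ATF4, as are TRIB3 (-0.85), DDIT3 (-0.83), CHAC1 (-0.83), ASNS (-0.45) and SESN2 (-0.69).

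A hypothesis from this pattern was that a wider amino acid response, of the kind ATF4 drives, may be lower in TNFα-treated BON cells. It was tested on further genes of that response, mostly tRNA ligases and amino acid transporters, listed before their values were looked at. Of the 24 tested, 15 fell in BON and 21 lay below 0, with a median log2 change of -0.304, and the median was -0.36 both after quantile normalization again and after median centring. SLC7A1 (-0.52, SE 0.05), SARS1 (-0.46, SE 0.06), NARS1 (-0.44, SE 0.06) and CEBPG (-0.41, SE 0.05) had large falls, whereas ALDH18A1 (0.14) and ALDH1L2 (0.06) did not pass. The list lay below other genes (camera p = 1.23e-10; p = 0.0221 with an estimated correlation), and its median in NCI-H295R was 0.02. Medium use and cell density, which also alter these genes, were not measured on the arrays and remain open.

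KYNU, the kynureninase gene, rose in BON (log2 1.17, SE 0.11, limma adjusted p = 0.0085) beside TDO2, and its interaction passed (limma adjusted p = 0.0392), with NCI-H295R below the filter level. Other single genes that rose were CLDN1 (log2 1.95, SE 0.06), DUOX2 (1.66), CEACAM7 (1.85), CEACAM5 (1.12), CEACAM6 (1.01), OLFM4 (1.10) and KRT7 (0.98). In untreated BON, KYNU (3.42) and DUOX2 (3.44) lay near the filter level, so the sizes of their rises are not exact. The trace amine receptor gene TAAR1 rose (log2 2.03, SE 0.21) and the nearby TAAR3P, VNN3P and VNN2 also passed as risen in limma, from untreated levels below the filter (2.32, 2.68 and 2.92), so the sizes of their changes are not given. VNN1 did not pass (limma adjusted p = 0.134).

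That neighbouring genes may rise together in BON was tested as a hypothesis on the 389 protein-coding genes that rose at least 1.5-fold. Neighbours were consecutive among the tested protein-coding genes in the order of GRCh38.p14, so genes that were not tested may lie between them. They formed 28 adjacent pairs, against a mean of 10.2 and a highest value of 23 in 10000 random draws of as many genes from 14752 (permutation p = 1e-04, one-sided, the smallest these draws can give). Pairs included TNF with LTB, CXCL10 with CXCL11, OAS1 with OAS3, CAV2 with CAV1, TAP1 with PSMB9, and SLC4A4 with NPFFR2. No genes were held out, so pairs already named as risen, such as TNF with LTB, count among the 28. The p therefore does not come from data independent of the rises that prompted the test. Some pairs are related genes of similar sequence, such as CEACAM5 with CEACAM6 and RTL8B with RTL8C, whose probes cannot be assumed to be independent.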
